A study of Petromyzon marinus with 46 samples.

How the data were processed

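Whole embryos of the sea lamprey were sampled at 22 times from 3 to 72 hpf. Per the labels, gametes were stripped from mature adults, embryos were kept in dilute Holtfreter's solution, total RNA was extracted with Trizol and dithiothreitol from pools of snap-frozen embryos, and libraries were prepared and sequenced by a company with its eukaryotic mRNA workflow. The deposited table gives raw counts per gene for each library, with no normalization. The submitters' processing notes name HISAT2 2.2.1 and StringTie 2.2.1; the role of each, the genome build and the strand setting are not given in the sources used here. The deposited annotation gives the start and end of 25385 gene models, the same number as the count table, of which 130 are marked as pseudogenes and 2518 had no counts in the 46 libraries. The count table held 2 further sample columns that match none of the 46 sample labels and are not used here.

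Each time point was a group, with 3 libraries at 12 and 39 hpf and 2 elsewhere. Depth ran from 53450480 to 117506779 counts per library. Shares of counts carry exact Clopper-Pearson 95% intervals, and floors for a count of 0 are 3 counts of the scaled library total, or of the group's total where a group is compared; both cover counting error only, since reads are not independent molecules. Libraries of the same time were compared by a chi-square test over genes with at least 20 counts; the statistic over its degrees of freedom was between 8.25 and 826 for 26 pairs. The test can find a library present more than once, which was not seen, and does not show that pools are separate replicates. No libraries were summed. The count columns of 12 hpf are named so that replicates 2 and 3 could be 2 libraries of the same sample; the labels call all 3 biological replicates and they were used so. Their statistic was 15.9, against 292 and 261 with replicate 1, and their rDNA shares were 11.4% and 11.9% against 24.6%, while the correlations of log CPM were alike (0.980 for the 3 pairs). Replicates 2 and 3 of 39 hpf were also the closest of their time, with a statistic of 11.96 against 118.9 and 115.7 with replicate 1. Their rDNA shares were 3.25% and 3.05% against 0.616%, and no alternative summed them. Whether equal replicate numbers pair libraries across times was checked by correlating replicate differences between 231 pairs of time points; the correlations were between -0.0826 and 0.0532, so the main test has no pairing and a block for replicate number is an alternative.

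Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the time groups, which left 19597 genes, libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit, glmQLFTest) was fitted once to all 46 libraries so that groups share the estimate of the spread. The comparisons were 24 with 3 hpf, 48 with 24 hpf, 72 with 48 hpf and 72 with 3 hpf, all time points at once, and the 21 steps between neighbouring times. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within each comparison) and an absolute log2 fold change of 1 or more; for all time points at once the second condition was a range of at least 2-fold. A sustained rise or fall began at the first time called against 3 hpf where the next time was called in the same direction. Log CPM used a prior count of 2 and the fit a prior count of 0.125. Folds against a group without counts are lower bounds with 3 counts over the group. Principal components were taken of log2 CPM.

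For 24 gene lists on egg, germ line, germ layer, signalling, cell cycle, translation, respiration, splicing, transcription, chromatin, Hox, adhesion, stress, differentiated-tissue and foreign-cell genes, camera (limma 3.58.1) was run with a preset correlation of 0.01 for each of the 4 comparisons, and p-values were adjusted over the 96 tests together; an estimated correlation was the alternative. A list symbol took every gene model of that name and its paralogs with a letter from A to F or a hyphenated suffix. That rule also took BRAF in the mesoderm list, RHOA, RHOB, RHOF and INSC in the differentiated-tissue list, and CPD and CPE in the list with adult liver, and lists without these were an alternative, as was 1 gene per name. List medians are given as fitted and with undetected genes at their bound.

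Genes named in the report follow a rule: in each of the 4 comparisons, the 6 called genes with the largest rise and the 6 with the largest fall that carry a symbol, have a mean of at least 10 CPM in the higher group and no overlap of libraries between the groups, with 1 gene per symbol; in each list up to 2 called members with the largest rise and 2 with the largest fall; a panel of 32 landmark genes, called or not; and at each onset up to 2 genes with the largest change at 72 hpf and a maximum mean of at least 10 CPM. The report prints a part of these, and some genes that meet the rule are not reported here. The groups, comparisons, lists, naming rule and most other settings listed below were fixed before the data were examined.

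The steps were tested on simulated data of 18119 genes, 200 of them changed from 36 hpf on. Of simulated 4-fold changes 100% were called from 24 to 48 hpf and of 2-fold changes 49%, with 3 unchanged genes called. An onset at 36 hpf was found for 100% of 4-fold rises and 98% of 4-fold falls. All simulated genes had the same dispersion, and only genes above a minimum expected count were changed, equally in both directions. No shift in the make-up of the libraries was simulated, so these rates do not carry over to low counts or to the choice of scaling.

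Other settings tried were DESeq2 size factors (DESeq2 1.42.0), the DESeq2 test, library totals without factors, upper-quartile factors, no filter on low counts, a stricter filter of 10 CPM in 2 libraries, a replicate block, the adjusted p alone, a test against a 2-fold change, only the libraries of the times compared, leaving out each replicate, 3 consecutive time points or a 6 hpf baseline for onsets, and an estimated correlation for lists. Added after the data had been seen were leaving out 180 genes (those annotated as ribosomal RNA, and on 2 unplaced contigs all genes between or within 20000 bp of them) and scaling by the totals of the rest, the log2 rDNA share as a covariate, leaving out libraries with over 20% of counts at these genes, summing replicates 2 and 3 of 12 hpf, and the list alternatives named above. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.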

Results

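Gene expression was measured by bulk RNA sequencing in whole wild-type sea lamprey (Petromyzon marinus) embryos sampled at 22 times from 3 to 72 hours post fertilization (hpf). The series had 46 libraries, 3 at each of 12 and 39 hpf and 2 at every other time, each from a pool of snap-frozen embryos. Total counts per library ran from 53450480 (69 hpf, replicate 2) to 117506779 (30 hpf, replicate 1) (median 74260000). Between 15156 genes (3 hpf, replicate 2) and 17733 genes (51 hpf, replicate 2) had at least 10 counts. Levels are given below as CPM (counts relative to the scaled library total), mean ± SD with n = 2 libraries unless another n is stated. A count of 0 allows up to 3 counts, which is between 0.0217 CPM (30 hpf, replicate 1) and 0.0836 CPM (69 hpf, replicate 2) of the scaled library totals, and such floors cover counting error only. Gene positions are those of the deposited annotation, whose genome build is not given in the sources used here. Several gene models can carry the same symbol; the identifier then tells them apart, the number of models is given, and the identity and level of each such model are uncertain.

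Libraries lay along a curve broadly in order of developmental time up to 66 hpf, and the 72 hpf libraries lay between those of 66 and 69 hpf on the leading component. The leading 2 principal components of log2 CPM held 64% and 11.4% of the variance. Within a time point the correlation of log CPM across genes, which are not independent replicates, was between 0.964 and 0.988 for the 26 pairs of libraries. A group of 180 genes, annotated as ribosomal RNA or next to such genes on 2 unplaced contigs and called rDNA genes below, took between 0.616% (39 hpf, replicate 1) and 32.4% (36 hpf, replicate 2; exact Clopper-Pearson 95% interval 32.40 to 32.43%) of the counts, with a median of 4.66%. Most genes of the group lie on chromosomes 23 and 43, but no gene of it outside the 2 contigs took more than 0.0543% of a library. At the times compared in detail these shares were 1.52% and 2.11% (3 hpf), 11.6% and 24.6% (24 hpf), 3.29% and 7.81% (48 hpf), and 1.65% and 0.672% (72 hpf). The p-values for single genes measure the spread between pools of embryos, which the labels call biological replicates. Those of the list tests compare a list with the other genes and also rest on a preset or estimated correlation between genes. Whether the pools came from the same cross is not given in the sources used here.

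**Figure D1:**
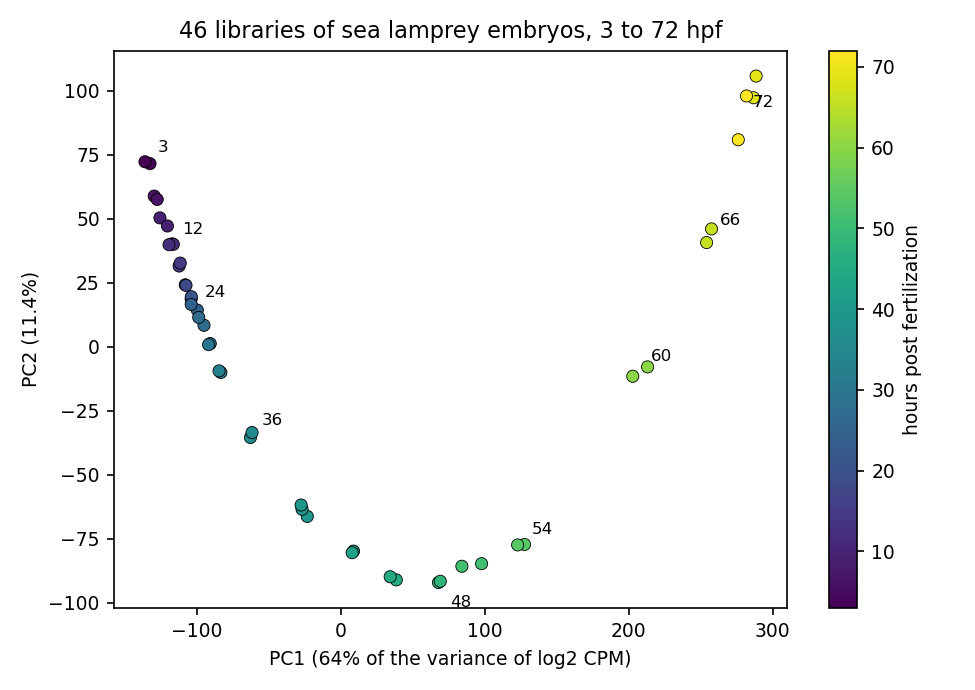
Each point is 1 of the 46 libraries on the first 2 principal components of log2 CPM (axes in units of the component scores), coloured by hours post fertilization. PC1 held 64% and PC2 11.4% of the variance, and the 72 hpf libraries lie between those of 66 and 69 hpf on PC1.

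CPEB1 (PM20837, chromosome 52, 7861289 to 7876058, 1 of 2 models of that name), a regulator of cytoplasmic polyadenylation of stored messages, went from 1690 ± 29.5 CPM at 3 hpf to 15.8 ± 2.73 CPM at 72 hpf. CCNA2 (PM10903, 1 of 2 models), which encodes a mitotic cyclin, went from 9680 ± 7.65 to 78.2 ± 60 CPM. In the opposite direction, SLC12A3 (PM13099, chromosome 25, 4626686 to 4655712, 1 of 4 models), a sodium chloride cotransporter, had no counts at 3 hpf and reached 5380 ± 322 CPM at 72 hpf. NEUROD1 (PM08303, 1 of 4 models), a proneural transcription factor, was highest in the middle of the series, at 171 ± 4.18 CPM at 45 hpf, and stood at 9.53 ± 0.93 CPM at 72 hpf. By edgeR's quasi-likelihood test of all time points at once, 15543 of 19597 genes tested (79.3%) changed, at an adjusted p under 0.05 and a range of at least 2-fold between time points.

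**Figure D2:**
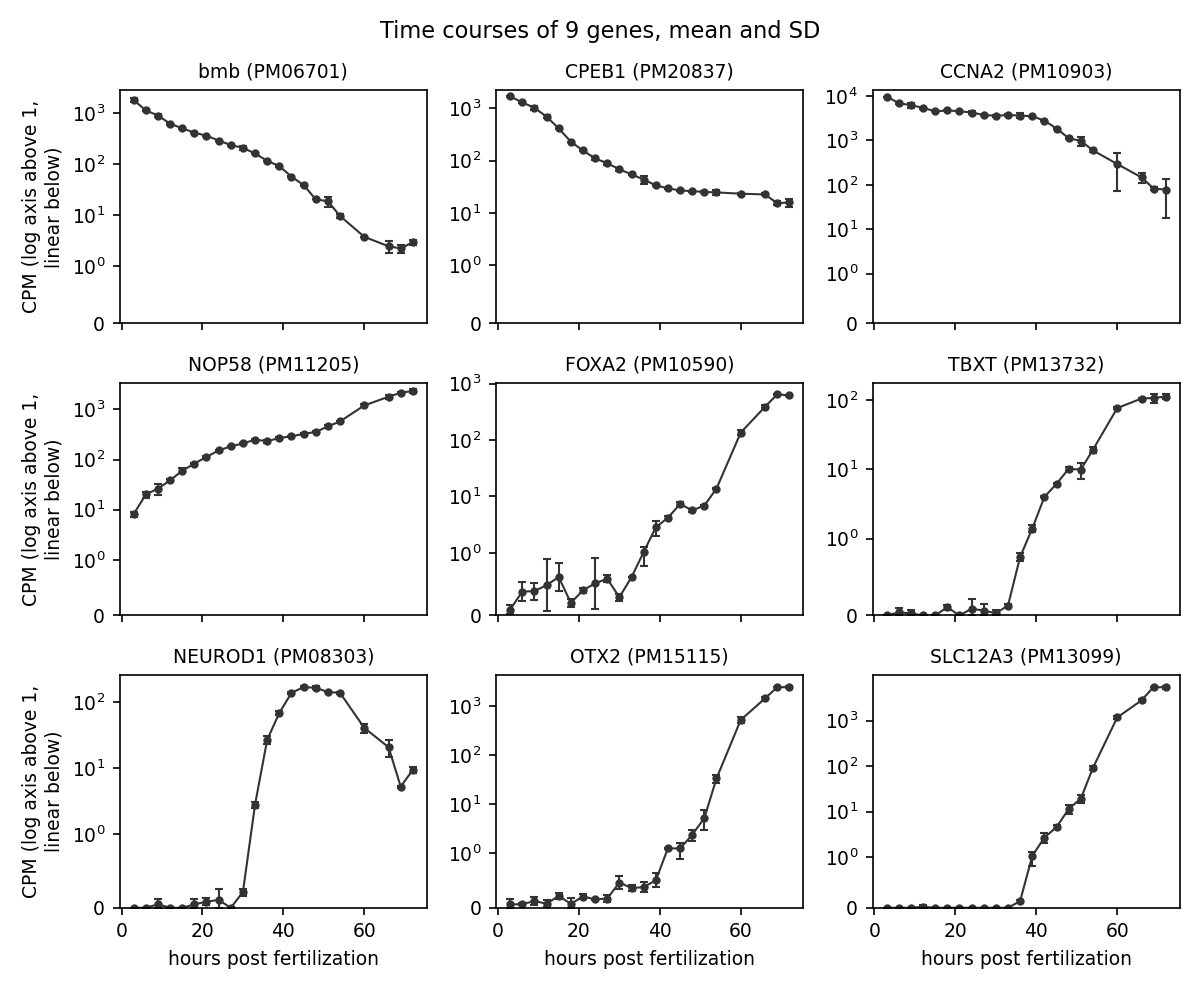
Mean CPM of 9 genes at the 22 sampled times (hours post fertilization); bars are the SD of 2 libraries (3 at 12 and 39 hpf), and the vertical axis is logarithmic above 1 CPM and linear below. CPEB1, bmb and CCNA2 declined, NEUROD1 peaked at 171 CPM at 45 hpf, and SLC12A3 reached 5380 CPM at 72 hpf.

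NOP58 (PM11205), a core protein of small nucleolar ribonucleoproteins, went from 8.14 ± 1.03 to 20.1 ± 2.65 CPM in the step from 3 to 6 hpf, in which 331 genes rose and 133 fell. That step had 464 calls, against 841 with library totals after the rDNA genes were left out and 5065 with the adjusted p alone. NEUROD1 (PM08303) went from 2.84 ± 0.281 to 27.2 ± 3.81 CPM between 33 and 36 hpf, and the 3 steps from 33 to 42 hpf had 181, 290 and 239 rising genes against 7, 83 and 10 falling genes. OTX2 (PM15115, 1 of 3 models), a head and anterior patterning factor, went from 33.3 ± 6.1 to 519 ± 68.7 CPM between 54 and 60 hpf, a step of 6 h with 1382 rising and 1633 falling genes. The following steps had 573 rising and 518 falling genes (60 to 66 hpf, 6 h), 545 and 1080 (66 to 69 hpf), and 135 and 152 (69 to 72 hpf). Between 15 and 33 hpf each 3 h step had at most 25 called genes, and the step from 18 to 21 hpf had 1 by edgeR, with 497 genes higher and 386 lower at an unadjusted p under 0.05. With library totals the step from 15 to 18 hpf had 94 calls, and with the rDNA share as a covariate 3, in place of 19. With the adjusted p alone the step from 33 to 36 hpf had 318 calls, against 2940 from 9 to 12 hpf, 1619 from 45 to 48 hpf and 2487 from 51 to 54 hpf. With the rDNA share as a covariate the step from 36 to 39 hpf had 194 calls in place of 373, and that from 69 to 72 hpf 188 in place of 287. The 21 steps together gave 8006 calls, adjusted within each step, and the steps differ in length.

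**Figure D3:**
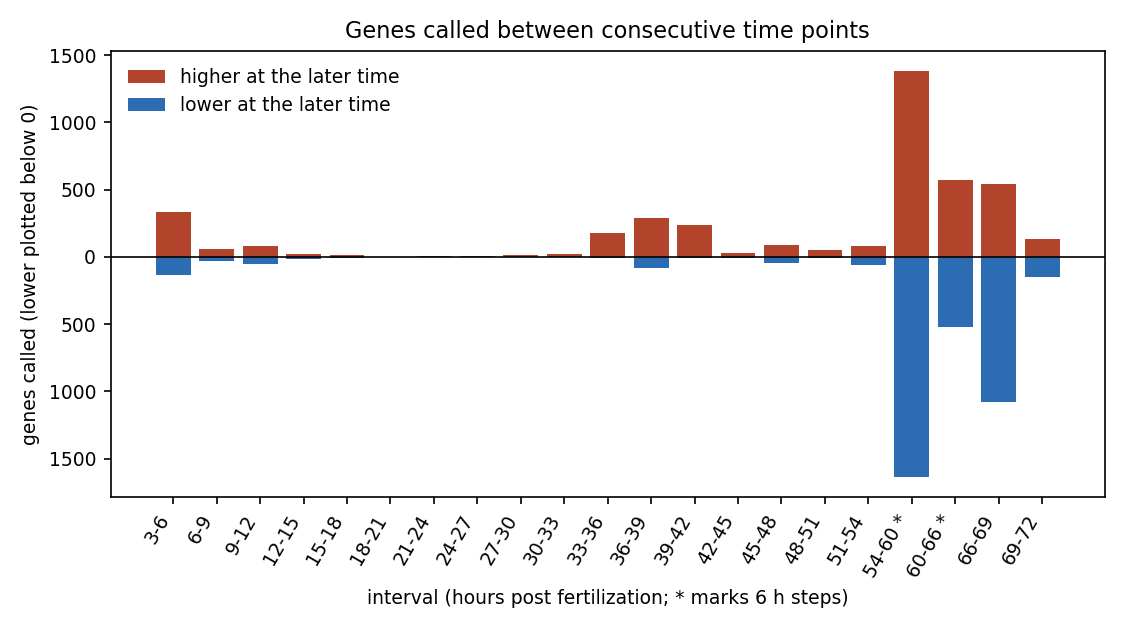
Genes called between each time point and the one before (hours post fertilization), with genes higher at the later time above 0 and genes lower at the later time below 0; asterisks mark the 2 steps of 6 h. The step from 54 to 60 hpf had 1382 genes higher and 1633 lower, and the step from 18 to 21 hpf had 1.

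From 3 to 24 hpf, NOP58 (PM11205, chromosome 19, 8783951 to 8795528) went from 8.14 ± 1.03 to 152 ± 3.68 CPM (log2 change 4.22, adjusted p = 5.37e-23), and EIF4B (PM08283, chromosome 10, 5296294 to 5332740, 1 of 2 models), a translation initiation factor, went from 10.3 ± 1.95 to 193 ± 9.23 CPM (log2 change 4.24, adjusted p = 2.83e-23). PUM3 (PM01331, unplaced scaffold), a nucleolar Pumilio-family protein, went from 1.14 ± 0.192 to 22.1 ± 1.05 CPM. WDR46 (PM06207) overlaps another gene model, so its rise from 2.14 ± 0.0807 to 32 ± 0.286 CPM is uncertain in its source; the same holds for REXO1 (PM16011, 1.13 ± 0.0637 to 18.4 ± 2.7 CPM) and NDUFS1 (PM15849, 4.59 ± 1.15 to 69.1 ± 32.6 CPM).

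Among the falls from 3 to 24 hpf, MKKS (PM09061, chromosome 12, 3617489 to 3627524), a chaperonin-like protein, went from 36.1 ± 0.553 to 0.708 ± 0.221 CPM (log2 change -5.65, adjusted p = 2.44e-07). AIMP2 (PM05247, chromosome 3, 19103375 to 19110958), a scaffold of the aminoacyl-tRNA synthetase complex, went from 51.9 ± 1.82 to 2.51 ± 0.00906 CPM (log2 change -4.37, adjusted p = 2.82e-20). SPRY3 (PM10994), of the Sprouty antagonists of receptor tyrosine kinase signalling, went from 350 ± 66.8 to 22 ± 4.14 CPM, and DSE (PM22624, 1 of 3 models) from 84.6 ± 3.68 to 5.34 ± 1.14 CPM. POLR3F (PM07060, 79.2 ± 13.1 to 2.03 ± 0.0818 CPM) and ESM1 (PM09357, 55.8 ± 11 to 2.45 ± 0.59 CPM) overlap other genes, and the source of their counts is uncertain.

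Of the 24 gene lists, 3 passed camera's test from 3 to 24 hpf. Mitotic cyclins and M-phase regulators were lower, with 13 of 29 tested genes falling and 3 rising (median log2 change -0.77, adjusted p = 0.001; adjusted p = 0.0521 with an estimated correlation). PLK1 (PM22321), a mitotic kinase, fell from 4390 ± 197 to 1390 ± 20.2 CPM and WEE1 (PM23657, 1 of 2 models), which restrains entry into mitosis, from 143 ± 9.33 to 33.7 ± 0.39 CPM. FZR1 (PM18862), an activator of the anaphase-promoting complex, rose from 6.94 ± 0.6 to 33.7 ± 3.78 CPM. Spliceosome genes were lower, with 12 of 40 falling and 4 rising (median -0.64, adjusted p = 0.00402; adjusted p = 0.497 with an estimated correlation), a call that ended with library totals after the rDNA genes were left out. SNRPG (PM08019) fell from 120 ± 24.4 to 34.5 ± 1.88 CPM and PRPF3 (PM20680) rose from 33.6 ± 1.29 to 187 ± 3.84 CPM. Genes of mRNA deadenylation and decay were higher, with 15 of 51 rising and 6 falling (median 0.41, adjusted p = 0.0408; adjusted p = 0.168 with an estimated correlation). That call also ended with DESeq2 size factors (adjusted p = 0.0872), upper-quartile factors (0.0904) and 1 gene per name (0.34). YTHDF2 (PM09951, 1 of 3 models), a reader of methylated messages, rose from 16.4 ± 1.42 to 116 ± 7.02 CPM, and CNOT9 (PM05724), of the CCR4-NOT deadenylase, from 0.758 ± 0.216 to 6.74 ± 0.253 CPM.

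The remaining lists did not pass from 3 to 24 hpf. In all list counts and medians, models of the same name count separately. The 41 oocyte and egg genes carried 17 names, with 9 models named ZP3, 8 named ZP4 and 4 named ZPD. CDH2 was the name of 23 of the 84 neural genes and of 23 of the 98 adhesion genes. Of the 59 differentiated-tissue genes 10 were named CRYAB. Basal transcription had 28 of 90 genes rising and 15 falling. GTF2F1 (PM16080) rose from 8.96 ± 1.1 to 63.3 ± 2.95 CPM and MED17 (PM19622) fell from 109 ± 3.25 to 21.5 ± 0.636 CPM. Respiratory chain genes had 22 of 85 rising and 16 falling. Mitochondrial ribosomal proteins had 17 rising and 17 falling of 74, and cytoplasmic ribosomal proteins 8 and 14 of 89. Chromatin and DNA methylation genes had 19 of 64 rising and 4 falling. SUV39H2 (PM09768), a histone methyltransferase, fell from 746 ± 58.3 to 241 ± 10.1 CPM. Oocyte and egg factors had 8 of 41 rising and 6 falling. CPEB1 (PM20837) fell from 1690 ± 29.5 to 110 ± 5.27 CPM, and npm2 (PM03031), a nucleoplasmin of eggs, rose from 5.37 ± 0.784 to 21.2 ± 0.589 CPM. Germ line and piRNA genes had 8 of 29 rising and 1 falling. DNA replication genes had 5 rising and 11 falling of 45 and G1 regulators 5 and 8 of 51. In a list of Nodal, BMP, Wnt and FGF signals, antagonists and feedback genes 14 of 91 rose and 10 fell. That list also holds Hedgehog and Notch pathway genes and is called the signals list below. SALL1 (PM21375, 1 of 3 models) of the pluripotency list rose from 169 ± 3.67 to 1130 ± 18 CPM. That list had 6 of 37 rising and 4 falling (5 and 4 when adjusted over the list alone). Endoderm (2 and 3 of 27), mesoderm (4 and 2 of 43), neural (9 and 11 of 84) and neural crest (3 and 5 of 39) lists had few calls. When adjusted over the list alone these were 1 and 3, 2 and 2, 8 and 11, and 2 and 5. Epidermal genes had 6 of 53 rising and 8 falling. Hox genes had 7 rising and 4 falling of 38 and stress genes 8 and 7 of 33. Adhesion genes had 7 rising and 17 falling of 98 (7 and 16 when adjusted over the list alone), and differentiated-tissue genes 5 and 11 of 59 (5 and 10 when adjusted over the list alone). In the list of sperm, follicle, blood and adult liver 1 of 24 genes rose, which did not pass when adjusted over the list alone, and 23 did not pass. With library totals, medians turned from -0.21 to 0.02 (DNA replication), -0.07 to 0.24 (respiratory chain) and -0.08 to 0.12 (epidermal genes). With library totals after the rDNA genes were left out, that of oocyte and egg factors turned from -0.43 to 0.09.

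By edgeR's quasi-likelihood test 3399 genes rose and 2248 fell from 3 to 24 hpf, so that 60.2% of the called genes were higher. That share was 51.3% with DESeq2 size factors, 50.6% with upper-quartile factors, 80.3% with library totals (1132 falling) and 90.7% with library totals after the rDNA genes were left out (5836 rising, 598 falling). These scalings moved the median of all genes by -0.12, -0.13, 0.30 and 0.56 on the log2 scale.

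From 24 to 48 hpf, OSR1 (PM13836, chromosome 27, 7184518 to 7216236, overlapping a gene model of unknown product), a mesodermal transcription factor, went from 0 to 54.3 ± 3.39 CPM, at least 3000-fold higher (floor of 3 counts over the group, adjusted p = 1.94e-17). SHH (PM05492, chromosome 4, 327697 to 351591, 1 of 3 models), the Hedgehog ligand, went from 0 to 22 ± 3.4 CPM, at least 1220-fold higher. FGF18 (PM07969, 1 of 2 models), a growth factor, went from 0 to 25.1 ± 0.267 CPM, at least 1390-fold higher. FGFR2 (PM08783, 1 of 3 models; 22.7 ± 1.17 CPM at 48 hpf), SP9 (PM05612, 1 of 2 models; 21.5 ± 0.531 CPM) and GSG1L (PM13336, 1 of 3 models, overlapping a model of unknown product; 21 ± 1.47 CPM) also rose from 0. SPSB1 (PM14129, chromosome 28, 5291574 to 5383334), a substrate adaptor of ubiquitin ligases, fell from 508 ± 21.6 to 22.4 ± 1.21 CPM (log2 change -4.50, adjusted p = 6.87e-26). BTG3 (PM24279), an antiproliferative factor, fell from 183 ± 12.6 to 12.6 ± 3.11 CPM, and bmb (PM06701, chromosome 6, 1621572 to 1631032), a gene needed for nuclear fusion in cleaving zebrafish embryos, from 290 ± 6.13 to 20.5 ± 0.14 CPM. P4HTM (PM19403), ATP6V0A2 (PM06499) and TTC38 (PM20796), the latter 2 overlapping other gene models, fell by 4.06, 3.90 and 3.88 on the log2 scale.

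Cytoplasmic ribosomal protein genes rose as a group from 24 to 48 hpf: 80 of 89 tested rose and 9 did not pass, with the same 80 count when adjusted over the list alone (median with undetected genes at their bound 3.71, adjusted p = 2.33e-47; adjusted p = 0.00517 with an estimated correlation). RPL23 (PM05528) rose from 0.5 ± 0.197 to 62 ± 3.77 CPM and RPS14 (PM03363) from 0.5 ± 0.0526 to 63.4 ± 4.87 CPM. Hox genes, which pattern the body axis, had 19 of 38 rising and 2 falling (22 and 2 when adjusted over the list alone; median 2.98, or 2.34 with undetected genes at their bound; adjusted p = 2.27e-05, and adjusted p = 0.012 with an estimated correlation). HOXA5 (PM05599, 1 of 2 models) went from 0 to 3.72 ± 0.493 CPM, and HOXC11 (PM03795) fell from 3.02 ± 0.234 to 0.66 ± 0.0716 CPM.

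Mesoderm genes had 22 of 43 rising and 4 falling (median 1.29, bounded 1.23, adjusted p = 8.68e-04; adjusted p = 0.024 with an estimated correlation). DLL1 (PM15692, 1 of 3 models), a Notch ligand, went from 0 to 20.8 ± 2.25 CPM. Neural ectoderm genes had 30 of 84 rising and 6 falling (median 1.11, bounded 1.06, adjusted p = 3.13e-04; adjusted p = 0.024 with an estimated correlation). That call ended with 1 gene per name. NEUROD1 (PM08303, chromosome 10, 6044110 to 6065686) went from 0.108 ± 0.153 to 167 ± 8.78 CPM and EN1 (PM11230), a midbrain and hindbrain homeobox gene, from 0 to 17.4 ± 0.687 CPM. FEZF2 (PM16361), a forebrain factor, fell from 129 ± 4.04 to 23.4 ± 0.65 CPM. Neural crest genes had 16 of 39 rising and 2 falling (17 and 2 when adjusted over the list alone; median 1.55, bounded 1.07, adjusted p = 4.2e-04; adjusted p = 0.00517 with an estimated correlation). TWIST1 (PM08493) went from 0 to 16.3 ± 0.0339 CPM, at least 902-fold higher, and FOXD3 (PM16104, 1 of 3 models) from 0.089 ± 0.0385 to 31.5 ± 0.334 CPM. Endoderm genes had 13 of 27 rising and 2 falling (14 and 2 when adjusted over the list alone; median with undetected genes at their bound 2.42, adjusted p = 0.0084, and adjusted p = 0.0343 with an estimated correlation). SOX17 (PM18763), an endoderm factor in jawed vertebrates, fell from 16.5 ± 1.56 to 4.1 ± 0.713 CPM.

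The signals list had 32 of 91 genes rising and 14 falling from 24 to 48 hpf (33 and 14 when adjusted over the list alone). Its median was 1.13, with an adjusted p of 0.00476 by camera. The adjusted p was 0.0912 with an estimated correlation and 0.0719 with 1 gene per name. AXIN1 (PM04931, 1 of 4 models), a Wnt antagonist, fell from 21 ± 0.807 to 2.28 ± 0.497 CPM. Pluripotency factors had 12 of 37 rising and 2 falling (13 and 2 when adjusted over the list alone; median 0.61, adjusted p = 0.0275; adjusted p = 0.0842 with an estimated correlation). With 1 gene per name that list did not pass. MYCN (PM05028, chromosome 3, 11220437 to 11228831, 1 of 6 models) rose from 3.89 ± 0.655 to 818 ± 4.01 CPM and MYCL (PM12350) fell from 229 ± 5.19 to 16.4 ± 1.4 CPM. Respiratory chain genes had 17 of 85 rising and 5 falling (median 0.48, adjusted p = 1.1e-06; adjusted p = 0.208 with an estimated correlation). COX6B1 (PM18402) went from 1.68 ± 0.15 to 17.6 ± 1.85 CPM. Of mitochondrial ribosomal proteins 8 of 74 rose and 66 did not pass (median 0.41, adjusted p = 3.45e-05; adjusted p = 0.258 with an estimated correlation). Spliceosome genes had 3 of 40 rising and 1 falling (median 0.46, adjusted p = 3.63e-06; adjusted p = 0.293 with an estimated correlation). Mitotic genes were lower, with 5 of 29 falling and 24 not passing (median -0.34, adjusted p = 0.0265; adjusted p = 0.158 with an estimated correlation). That call ended with library totals (adjusted p = 0.065) and with upper-quartile factors. PLK1 (PM22321) fell from 1390 ± 20.2 to 158 ± 3.03 CPM.

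Lists that did not pass from 24 to 48 hpf were epidermal ectoderm (15 of 53 rising, 3 falling), adhesion (12 and 5 of 98) and differentiated tissues (10 and 1 of 59). The same held for stress (8 and 6 of 33), G1 regulators (5 and 6 of 51), basal transcription (3 and 7 of 90), chromatin (3 and 4 of 64), mRNA decay (2 and 6 of 51), germ line (3 and 2 of 29), and sperm, follicle, blood and adult liver (3 and 1 of 24, or 1 and 1 when adjusted over the list alone). Oocyte factors had 3 of 41 falling and 38 not passing, and DNA replication genes 3 of 45 falling and 42 not passing. With library totals, the medians of mRNA decay and of G1 regulators turned from -0.06 to 0.16 and from -0.02 to 0.14. GADD45B (PM16069, 1 of 2 models), a stress and growth-arrest gene of the G1 list, rose from 11.6 ± 0.16 to 1420 ± 41.1 CPM, CCNB3 (PM23992) fell from 68.8 ± 1.02 to 12.6 ± 1.91 CPM, and PIWIL2 (PM07665), a piRNA-binding Argonaute, fell from 16.8 ± 1.05 to 2.6 ± 0.511 CPM.

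By edgeR's quasi-likelihood test 1943 genes rose and 2363 fell from 24 to 48 hpf, and 45.1% of the called genes were higher. With library totals that share was 56.1% (median of all genes moved by 0.22), with upper-quartile factors 53.2% (0.17), and 889 genes rose under a stricter filter on low counts.

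From 48 to 72 hpf, WNK1 (PM19890, chromosome 48, 8610906 to 8776113, 1 of 3 models), a kinase that regulates sodium chloride cotransport, rose from 0.141 ± 0.2 to 1810 ± 165 CPM (log2 change 13.63, adjusted p = 1.55e-20). TDO2 (PM10197, chromosome 16, 1765354 to 1884894), a tryptophan-degrading enzyme, went from 0 to 243 ± 12.7 CPM, at least 11000-fold higher (adjusted p = 2.51e-15), and LTF (PM21620), a transferrin-family gene, from 0 to 14.2 ± 0.71 CPM, at least 635-fold higher. The sodium channel genes SCN2A (PM05785, 1 of 7 models) and SCN4A (PM05784) went from 0 to 34.9 ± 2.88 and 12.1 ± 1.53 CPM, and the amino acid transporter SLC43A2 (PM00878, 1 of 4 models) from 0 to 42.4 ± 1.95 CPM. GPR89B (PM23018, chromosome 62, 530421 to 550634), a Golgi pH regulator, fell from 23 ± 0.577 to 0.367 ± 0.0922 CPM (log2 change -5.94, adjusted p = 5.3e-24). ZDHHC6 (PM18023), TBC1D12 (PM17757), PRKD1 (PM10550), ABHD18 (PM10276) and STX17 (PM17409), each 1 of 2 or 3 models, fell by 5.84, 5.46, 5.40, 5.31 and 5.30 on the log2 scale. ZDHHC6 and STX17 overlap other gene models, so the source of their counts is uncertain.

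Cytoplasmic ribosomal proteins had 82 of 89 rising and 7 not passing from 48 to 72 hpf (84 rising when adjusted over the list alone; median 4.16, bounded 4.15, adjusted p = 1.42e-27; adjusted p = 0.024 with an estimated correlation). Spliceosome genes had 30 of 40 rising and 10 not passing (median 1.75, adjusted p = 3.22e-14; adjusted p = 0.0887 with an estimated correlation). SNRPA (PM20938) rose from 269 ± 1.79 to 2320 ± 129 CPM. Respiratory chain genes had 57 of 85 rising and 4 falling (median 1.48, adjusted p = 4.05e-10; adjusted p = 0.104 with an estimated correlation). COX5A (PM09620) rose from 13.4 ± 0.152 to 151 ± 6.93 CPM. Mitochondrial ribosomal proteins had 45 of 74 rising and 2 falling (median 1.37, adjusted p = 5.86e-08; adjusted p = 0.14 with an estimated correlation). MRPL41 (PM20543) rose from 2.38 ± 0.206 to 59.1 ± 0.171 CPM. Chromatin genes had 29 of 64 rising and 9 falling (median 0.89, adjusted p = 2.42e-04; adjusted p = 0.024 with an estimated correlation). DNMT3A (PM09942, 1 of 4 models), a DNA methyltransferase, rose from 7.81 ± 1.23 to 195 ± 24.7 CPM and NPM1 (PM14362, 1 of 2 models), nucleophosmin, from 209 ± 3.33 to 2010 ± 160 CPM. With library totals after the rDNA genes were left out, the medians were 3.31 (cytoplasmic ribosomal proteins), 0.90 (spliceosome), 0.63 (respiratory chain), 0.52 (mitochondrial ribosomal proteins) and 0.05 (chromatin).

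Endoderm and mesendoderm genes had 11 of 27 rising and 2 falling from 48 to 72 hpf (median 2.77, adjusted p = 0.0175; adjusted p = 0.0514 with an estimated correlation, and over the threshold with 1 gene per name). FOXA2 (PM15513, 1 of 3 models), an endoderm and midline factor, rose from 1.17 ± 0.0452 to 151 ± 4.2 CPM and HHEX (PM08710, 1 of 3 models, overlapping a model of unknown product) from 3.55 ± 0.513 to 519 ± 31.6 CPM. OTX2 (PM15115, chromosome 31, 10967764 to 11004071) rose from 2.37 ± 0.625 to 2410 ± 93 CPM; pluripotency factors had 11 of 37 rising and 7 falling, and neural genes 17 of 84 rising and 18 falling (17 and 17 when adjusted over the list alone). NEUROD1 (PM08303) fell from 167 ± 8.78 to 9.53 ± 0.93 CPM. Hox genes had 2 of 38 rising and 17 falling (median -0.92, below 0 under each scaling tried, adjusted p = 0.146), so the list did not pass. Mesoderm genes had 8 of 43 rising and 10 falling. CDX2 (PM10217) rose from 0.104 ± 0.0207 to 18.7 ± 1.95 CPM and DLL1 (PM15692) fell from 20.8 ± 2.25 to 1.4 ± 1.44 CPM. Neural crest genes had 8 of 39 rising and 7 falling. SNAI1 (PM23238), a regulator of epithelial-mesenchymal transition, rose from 35.2 ± 0.187 to 257 ± 5.8 CPM and TWIST1 (PM08493) fell from 16.3 ± 0.0339 to 3.5 ± 0.13 CPM. Of the signals list, 21 of 91 rose and 19 fell. BMP2 (PM10502) rose from 0.534 ± 0.103 to 26.2 ± 3.83 CPM and ADMP (PM04580) from 1.78 ± 0.131 to 56.5 ± 5.42 CPM.

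M-phase genes had 11 of 29 rising and 4 falling from 48 to 72 hpf (median 0.69, which turned to -0.05 with library totals; adjusted p = 0.285). WEE1 (PM23657) rose from 10.8 ± 0.732 to 1130 ± 108 CPM, whereas CCNA2 (PM10903) fell from 1120 ± 25.3 to 78.2 ± 60 CPM. DNA replication genes had 5 of 45 rising and 13 falling. CDC7 (PM11852) fell from 21.7 ± 0.172 to 1.36 ± 0.335 CPM. G1 regulators had 13 rising and 13 falling of 51 (14 and 14 when adjusted over the list alone). Basal transcription genes had 32 of 90 rising and 13 falling. POLR2H (PM06272) rose from 24.4 ± 1.21 to 208 ± 1.35 CPM and TBP (PM06682), the TATA-binding protein, fell from 191 ± 14.6 to 31.6 ± 0.661 CPM. Genes of mRNA decay had 17 of 51 rising and 10 falling. CNOT1 (PM13257) rose from 93.5 ± 1.95 to 707 ± 44 CPM and DCP1B (PM16409), a decapping cofactor, fell from 169 ± 0.303 to 16 ± 2.8 CPM. Stress genes had 11 of 33 rising and 4 falling (adjusted p = 0.0506). FOS (PM15624, 1 of 4 models) rose from 0.853 ± 0.00817 to 106 ± 1.81 CPM. The other lists had 17 of 53 rising and 11 falling (epidermal ectoderm), 3 and 6 of 41 (oocyte factors), and 4 and 5 of 29 (germ line). Adhesion genes had 17 rising and 13 falling of 98 (17 and 12 when adjusted over the list alone). Differentiated-tissue genes had 8 rising and 8 falling of 59, and sperm, follicle, blood and adult liver genes 5 and 2 of 24 (5 and 1 when adjusted over the list alone). With library totals, list medians turned from 0.42 to -0.31 (basal transcription), 0.44 to -0.36 (mRNA decay), 0.52 to -0.24 (pluripotency factors), 0.25 to -0.37 (oocyte factors) and 0.44 to -0.19 (sperm, follicle, blood and adult liver). Those of adhesion (0.08 to -0.59), neural (0.06 to -0.64), neural crest (0.03 to -0.75) and differentiated-tissue genes (0.03 to -0.74) turned too, and that of epidermal ectoderm went from 0.61 to 0. With library totals after the rDNA genes were left out the same medians were below 0, except 0 for epidermal ectoderm. With DESeq2 size factors the medians turned from -0.10 to 0.10 (DNA replication) and from -0.06 to 0.14 (germ line), and went from -0.19 to 0 (signals).

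By edgeR's quasi-likelihood test 4274 genes rose and 4868 fell from 48 to 72 hpf, and 46.8% of the called genes were higher. With library totals 2547 rose and 7405 fell (25.6% higher, median of all genes moved by -0.78), and with library totals after the rDNA genes were left out 2440 rose and 7629 fell (24.2% higher, median moved by -0.85). DESeq2 size factors moved the median by 0.20 and turned the majority, with 4894 rising and 4351 falling (52.9% higher), and the DESeq2 test gave 4743 and 4397 (51.9%).

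Over the whole interval from 3 to 72 hpf, SLC12A3 (PM13099) rose to 5380 ± 322 CPM from 0, at least 230000-fold (adjusted p = 5.2e-22), and WNK1 (PM19890) to 1810 ± 165 CPM, at least 77300-fold. SLC5A8 (PM11608, 1 of 4 models), a sodium-coupled monocarboxylate transporter, rose to 661 ± 14.9 CPM, at least 28200-fold. The gene named Prepronociceptin (PM13931), a neuropeptide precursor, rose from 0 to 1050 ± 60.7 CPM. MKKS (PM09061) fell from 36.1 ± 0.553 CPM to 0, at least 995-fold. CHAC1 (PM10711), a glutathione-degrading enzyme, fell from 546 ± 107 to 0.808 ± 0.256 CPM (log2 change -9.43, adjusted p = 8.9e-27), and bmb (PM06701) from 1800 ± 152 to 2.97 ± 0.356 CPM (log2 change -9.23, adjusted p = 6.21e-31). SH3YL1 (PM13959) fell by 10.04 on the log2 scale, and TMEM268 (PM12177, overlapping LAMC1) and SLIT2 (PM11050, 1 of 4 models) fell to 0 from 35.3 ± 2.43 and 15.5 ± 2.48 CPM.

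Of cytoplasmic ribosomal proteins, 86 of 89 rose from 3 to 72 hpf and 1 fell. The median was 8.22, or 8.06 with undetected genes at their bound (adjusted p = 1.65e-26; adjusted p = 0.0256 with an estimated correlation). RPS14 (PM03363) rose from 0.473 ± 0.21 to 1380 ± 34.4 CPM. Respiratory chain genes had 60 of 85 rising and 8 falling (median 2.43, adjusted p = 5.86e-08; adjusted p = 0.158 with an estimated correlation). Mitochondrial ribosomal proteins had 49 rising and 8 falling of 74 (median 1.87, adjusted p = 1.21e-05; adjusted p = 0.221 with an estimated correlation). Spliceosome genes had 28 rising and 1 falling of 40 (median 1.72, adjusted p = 8.87e-08; adjusted p = 0.212 with an estimated correlation). PRPF39 (PM15506) rose from 14.5 ± 1.65 to 514 ± 36.5 CPM. Chromatin genes had 31 of 64 rising and 11 falling (median 0.96, adjusted p = 0.00149; adjusted p = 0.0386 with an estimated correlation). HDAC3 (PM10318) rose from 3.79 ± 0.494 to 136 ± 9.04 CPM and EHMT2 (PM12071) fell from 979 ± 129 to 82.5 ± 8.66 CPM. Basal transcription genes had 40 of 90 rising and 12 falling (median 0.79, adjusted p = 0.0304; adjusted p = 0.199 with an estimated correlation, and 0.065 with library totals). Endoderm genes had 17 of 27 rising and 3 falling (median 5.13, bounded 4.69, adjusted p = 0.0366; adjusted p = 0.0842 with an estimated correlation, and 0.15 with 1 gene per name). GSC (PM15137, 1 of 2 models), an organizer gene in other vertebrates, rose from 0 to 152 ± 2.5 CPM.

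**Figure D4:**
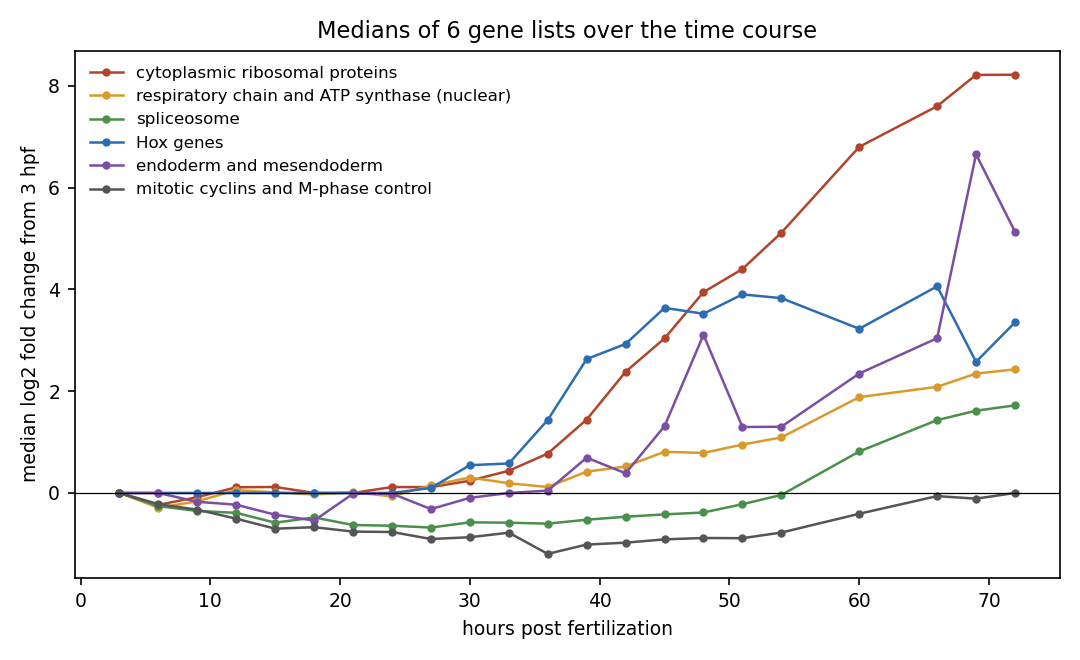
Median fitted log2 change from 3 hpf of 6 gene lists at each sampled time (hours post fertilization). The cytoplasmic ribosomal proteins reached a median of 8.22 at 72 hpf (8.06 with undetected genes at their bound) and the Hox genes 3.35 (2.62 at their bound); the M-phase median at 72 hpf, 0 here, turned to -0.14 with library totals, and the ribosomal protein median at 24 hpf, 0.12 here, was 0 with DESeq2 size factors.

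In the lists that did not pass from 3 to 72 hpf, neural genes had 41 of 84 rising and 16 falling, signals 41 and 16 of 91, and mesoderm 24 and 7 of 43. Epidermal ectoderm had 24 rising and 8 falling of 53, neural crest 17 and 5 of 39, pluripotency factors 17 and 6 of 37, and Hox genes 21 and 5 of 38. TBXT (PM13732, 1 of 2 models), the Brachyury gene, rose from 0 to 113 ± 9.25 CPM and SOX21 (PM19547) from 0 to 59.3 ± 5.71 CPM. FEZF2 (PM16361) fell from 275 ± 20.1 to 1.63 ± 0.514 CPM. HOXB7 (PM08359, overlapping a model of unknown product) fell from 71.4 ± 2.07 to 2.91 ± 0.23 CPM. Oocyte and egg factors had 5 of 41 rising and 7 falling. FBXO43 (PM13843), which holds eggs in meiotic arrest, fell from 1440 ± 50.4 to 290 ± 4.81 CPM. M-phase genes had 7 of 29 rising and 13 falling, DNA replication 9 and 17 of 45, G1 regulators 18 and 19 of 51, and mRNA decay 22 and 12 of 51. Germ line genes had 11 rising and 8 falling of 29, adhesion 24 and 17 of 98, stress 15 and 8 of 33, differentiated tissues 18 and 11 of 59, and sperm, follicle, blood and adult liver 10 and 3 of 24 (9 and 3 when adjusted over the list alone). With library totals the germ line median turned from 0.22 to -0.02.

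By edgeR's quasi-likelihood test 6423 genes rose and 5537 fell from 3 to 72 hpf, and under the stricter filter on low counts 3592 rose and 3659 fell. Library totals moved the median of all genes by -0.26 with 48.9% of the called genes higher, against 53.7% here. Over the 4 comparisons, 76 of the 96 list counts were the same when adjusted over the list alone and the others differed by at most 3 genes. In total 28 of the 96 list tests passed, 25 of them upward, and 10 held with an estimated correlation.

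Onset was taken as the first time at which a gene was called against 3 hpf there and at the next time. A sustained rise was found for 8222 genes, with a median onset of 36 hpf. A sustained fall was found for 6740 genes, with a median onset of 42 hpf; 832 genes had both. Rises that began between 6 and 15 hpf numbered 2337, those from 33 to 42 hpf 1350, and those from 54 to 69 hpf 2146. Falls numbered 1274, 904 and 2406. These windows leave out 18 to 30 and 45 to 51 hpf, where single times had 200 to 373 rises and 128 to 389 falls. Single times from 33 to 42 hpf had 200 to 507 rises and 111 to 332 falls, so that window as a whole does not stand out. The last window spans more hours than the others and holds the times sampled after gaps of 6 h. Only 12 and 39 hpf had 3 libraries. Onsets of a rise peaked there against the times beside them (931 at 12 hpf, 507 at 39 hpf). Falls did so at 12 hpf (580) but not at 39 hpf (290, against 332 at 42 hpf). With replicates 2 and 3 of 12 hpf summed there were 8406 rises and 6620 falls, and their onsets at 12 hpf are not reported here. Whether the extra library at 39 hpf or the longer gaps raised these numbers was not tested. Among early rises, RPS3A (PM05146, onset 12 hpf) reached 2640 ± 166 CPM at 72 hpf from 1.59 ± 0.135 CPM at 3 hpf. GSC (PM15137, 0.117 ± 0.106 CPM) and TBXT (PM13732, 0.129 ± 0.0246 CPM) had a called onset at 33 hpf, and SLC12A3 (PM13099, 0.134 ± 0.0299 CPM) and SLC5A8 (PM11608, 0.0987 ± 0.00238 CPM) at 36 hpf. WNK1 (PM19890) had a called onset at 42 hpf at 0.192 ± 0.109 CPM but was at 0.141 ± 0.2 CPM at 48 hpf and 2.75 ± 0.539 CPM at 54 hpf. These 5 onsets were calls near the floor against a 3 hpf group without counts. Among falls, STUB1 (PM05390, 188 ± 24.8 to 1.98 ± 0.145 CPM) began at 6 hpf, CHAC1 (PM10711) at 9 hpf, and AXIN1 (PM04931) at 12 hpf. SPSB1 (PM14129, 2010 ± 53.2 to 4.95 ± 1.25 CPM) began at 15 hpf, MYCL (PM12350) at 36 hpf and SCRIB (PM13861, 1180 ± 112 to 24.6 ± 4.97 CPM) at 51 hpf. All onsets share the 3 hpf libraries, and FOXA2 (PM10590, 1 of 3 models) had a called onset at 9 hpf at 0.389 ± 0.137 CPM and stood at 621 ± 20 CPM at 72 hpf.

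**Figure D5:**
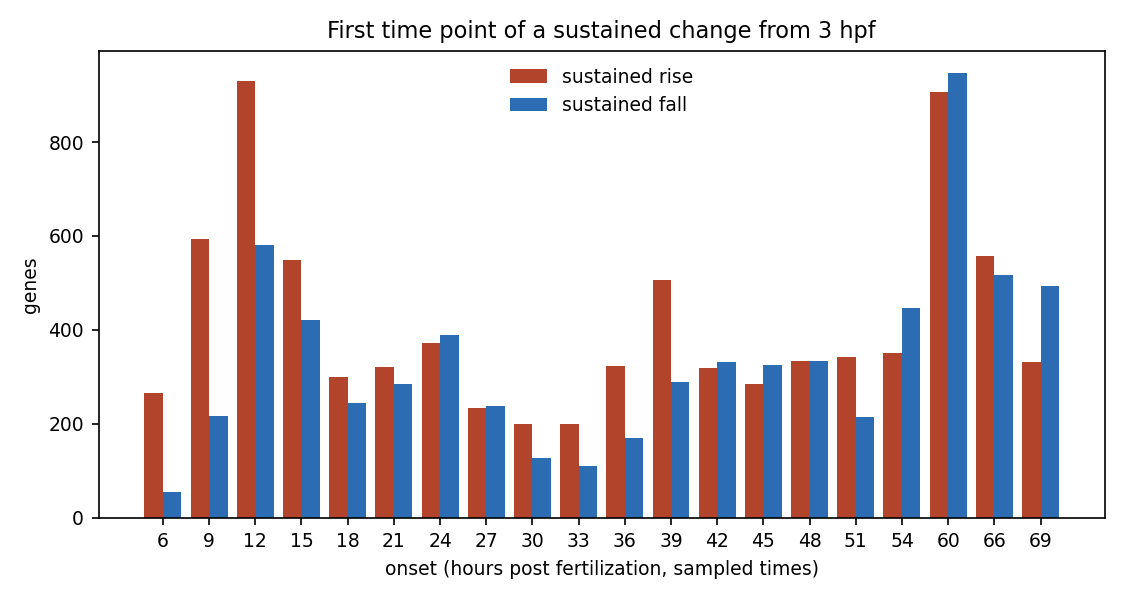
Number of genes whose sustained rise or fall from 3 hpf began at each sampled time (hours post fertilization; 72 hpf cannot be an onset). Onsets of a rise numbered 931 at 12 hpf and 907 at 60 hpf, and onsets of a fall 947 at 60 hpf. Only 12 and 39 hpf had 3 libraries, and 60 and 66 hpf each followed a gap of 6 h in sampling.

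The landmark genes chosen in advance were not all called, and a gene not called can still have changed by less than 2-fold. ZAR1 (PM19863, 1 of 2 models, overlapping PRSS16), a maternal-effect gene of eggs, was at 769 ± 3.88 CPM at 3 hpf, 576 ± 22.3 CPM at 24 hpf and 593 ± 30.4 CPM at 72 hpf and was not called in the 4 comparisons. MYC (PM10078) went from 80.4 ± 5.34 to 53.7 ± 3.42 CPM and the germ line helicase DDX4 (PM03488) from 6.09 ± 1.22 to 6.07 ± 0.93 CPM between 3 and 72 hpf, neither of them called. SOX2 (PM23515, 1 of 2 models) had an onset at 39 hpf and reached 759 ± 41.6 CPM, while the other model (PM21536, overlapping a model of unknown product) fell from 716 ± 1.74 to 98.7 ± 1.7 CPM. A second model of TBXT (PM13730) had an onset at 36 hpf and reached 115 ± 8.05 CPM, GATA4 (PM10025, 1 of 3 models) a called onset at 42 hpf (at 0.34 ± 0.00829 CPM) and 38 ± 3.75 CPM, and SNAI1 (PM23238) an onset at 60 hpf. No gene model carried the names NANOG, POU5F1, POU5F3, NODAL, CHRD, EOMES, WNT8A, BTG4, CCNB1, CCND1, DAZL, SOX3, VENTX, LIN28A or LEFTY2, so these are not analysed here.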

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

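The alternatives for the rDNA genes, for list membership and for the 12 hpf replicates summed were tests chosen after the data had been seen; all others were planned. Of the 546 results for named genes, 9633 alternative values were computed, of which 9269 kept their side of the threshold, 326 lost the call and 38 gained one. No named gene called in the main or the alternative setting reversed, and sign changes of genes called in neither were not counted. Over all genes tested, calls did turn in some settings, such as 1 gene from 3 to 24 hpf with the rDNA share as a covariate. For the 96 list tests 1104 of 1152 values held, 31 were lost and 17 gained. With library totals only, 1132 genes fell from 3 to 24 hpf, and 2547 rose and 7405 fell from 48 to 72 hpf. With library totals after the rDNA genes were left out, 5836 rose and 598 fell from 3 to 24 hpf, and 2440 rose and 7629 fell from 48 to 72 hpf. The scalings shift the median of all genes, as given with each comparison. Fewer genes are tested under the stricter filter of 10 CPM in 2 libraries: 1383 fell from 3 to 24 hpf, 889 rose from 24 to 48 hpf, 2760 rose from 48 to 72 hpf, 3592 rose and 3659 fell from 3 to 72 hpf, and 9489 changed over the time course. With the adjusted p alone, which drops the fold threshold, 5648 rose and 4831 fell from 3 to 24 hpf, 4607 rose and 4396 fell from 24 to 48 hpf, and the consecutive steps gave 41983 calls. The test against a 2-fold change, which is stricter by construction, gave 2063 rising and 1200 falling genes from 3 to 24 hpf. With an estimated inter-gene correlation 10 of the 28 list tests passed. The estimates were 0.302 (spliceosome), 0.207 (cytoplasmic ribosomal proteins), 0.152 (respiratory chain) and 0.145 (mitochondrial ribosomal proteins), against the preset 0.01. A preset below the estimate gives smaller p-values for such lists. Calls were also lost at estimates under the preset. These were pluripotency factors from 24 to 48 hpf (0.00894) and endoderm and mesendoderm from 48 to 72 and from 3 to 72 hpf (0.00504). Camera's unadjusted p moved from 0.00717 to 0.0117, from 0.00419 to 0.00589 and from 0.0103 to 0.0123. Each stayed under 0.05, so the calls were lost in the adjustment over the 96 tests (0.0842, 0.0514 and 0.0842). Why the unadjusted values rose was not tested. With a replicate block for pairing by replicate number, 3373 rose and 2227 fell from 3 to 24 hpf, 1917 and 2352 from 24 to 48 hpf, 4246 and 4848 from 48 to 72 hpf, and 6349 and 5516 from 3 to 72 hpf. Without the libraries over 20% rDNA, the counts in the same order were 3435 and 1772, 1656 and 2228, 4113 and 5153, and 6417 and 5555. Leaving out a replicate of a time compared, where the lone library is assumed to vary like the other groups, gave 3149 to 3564 rising and 1925 to 2231 falling genes from 3 to 24 hpf, 1583 to 1774 and 2223 to 2349 from 24 to 48 hpf, 3783 to 3962 and 4709 to 5155 from 48 to 72 hpf, and 5737 to 6109 and 5373 to 5607 from 3 to 72 hpf. Sustained rises numbered 7601 to 7665 and falls 6408 to 6518 without a 3 hpf replicate, and 15429 genes changed over the time course without replicate 3 of 12 and 39 hpf. With replicates 2 and 3 of 12 hpf summed, 3620 rose and 1998 fell from 3 to 24 hpf, the step from 12 to 15 hpf had 22 calls in place of 38, and the median onset was 33 hpf for 8406 rises and 45 hpf for 6620 falls; the cause was not tested. Depth limits genes under 0.0836 CPM in the library with the highest floor, where a count of 0 and a low level cannot be separated.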

Other observations

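The genes named and the sets described in this part, and the tests of the intraclass correlation, of the scaling and of interval length, were chosen after their results had been seen. A set of 211 genes rose from 24 to 51 hpf and fell from 54 to 72 hpf, against 532.7 in both lists if these were independent, and the contrasts share no library. A rise then a fall was thus rarer than for independent lists, and 1002 genes rose in both intervals, against 441.4. The set of 211 genes, out of 19597 tested, held 11 of 38 Hox genes, 7 of 43 mesoderm genes and 7 of 91 genes of the signals list. Lists can share genes, and DLL1 (PM15692) of this set counts in both the mesoderm and the signals list. From the neural list it held 4 of 84 genes, from pluripotency factors 3 of 37, from neural crest 3 of 39 and from epidermal ectoderm 1 of 53. The other lists had none in it. HOXC9 (PM05602, 1 of 3 models) went from 4.5 ± 0.645 CPM at 24 hpf to 62 ± 8.46 CPM at 51 hpf and 8.15 ± 1.66 CPM at 72 hpf (n = 2 at each time), and CDX4 (PM10872), a posterior patterning gene, from 0 to 15.3 ± 0.244 and 3.96 ± 1.25 CPM.

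A further 544 genes fell from 3 to 24 hpf and rose from 48 to 72 hpf, against 490.3 for independent lists. The other pairings were over independence too. In the same intervals 895 genes rose in both (against 741.3), 767 fell in both (558.4), and 923 rose and then fell (844.3). The excess is thus not particular to a fall and return. CAPN1 (PM15420, 1 of 7 models), a calpain protease, was at 430 ± 19.7 CPM at 3 hpf, 5.72 ± 1.32 CPM at 48 hpf and 209 ± 22.2 CPM at 72 hpf. NFKBIA (PM14376, 1 of 2 models), an inhibitor of NF-kappa-B, was at 73 ± 1.47, 4.5 ± 0.135 and 281 ± 7.58 CPM at the same times. On the mitochondrial sequence, 26 of 28 tested gene models rose from 3 to 72 hpf, with a median log2 change of 4.77. MT-CO1 rose by 4.98, MT-CO2 by 5.34, MT-CO3 by 5.45 and MT-ND1 by 5.35 on the log2 scale, each with an adjusted p under the threshold by edgeR's test.

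The share of counts at rDNA genes differed several-fold between libraries, also within a time point (2.73% and 17.3% at 27 hpf, 7.96% and 32.4% at 36 hpf). A permutation test of the 46 libraries over time points (100000 draws, one-sided) gave p = 0.00064, so the share varied with time beyond chance, which is consistent with a developmental change or with preparation in groups of neighbouring times. The intraclass correlation of the log2 share by time was 0.586 (95% interval 0.254 to 0.8), which reaches to both sides of the bound of 0.5. Whether differences between times or between libraries of a time were the larger part therefore cannot be told. Carry-over of ribosomal RNA and a developmental change of the share were not separated.

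Rises that started between 6 and 15 hpf numbered 2337. Transcripts absent from the 3 hpf embryo do not account for most of them: 8.64% of these genes were under 0.1 CPM at 3 hpf, against 51% of the rises from 33 to 42 hpf. The choice among the scalings tried does not account for most of them, since 2013 genes had such an onset with upper-quartile factors, the lowest number, all of them among the 2337. With DESeq2 size factors there were 2035, with library totals 3301 and with library totals after the rDNA genes were left out 4555, so the size of the wave depends on the scaling. Against rDNA carry-over there were 2086 such genes with the rDNA share as a covariate, 1929 of them shared. An increase of transcripts already present in the egg may explain much of this wave, which remains a hypothesis from these data. Whether longer poly(A) tails, new transcription or both raised the counts was not tested.

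Of the 4 steps after 54 hpf, 3 had more calls than any step before, and the step from 69 to 72 hpf (287) did not. At 6 h, the step from 54 to 60 hpf had 3015 calls against at most 1313 in the 6 h spans before 54 hpf, also beyond them under each scaling tried (3699 against 2432 at the closest), so its length does not account for it, while the step from 60 to 66 hpf had 1091, which its length could account for. The step from 66 to 69 hpf, of 3 h, had 1625 calls against at most 464 in the 3 h steps before 54 hpf, but the span from 66 to 72 hpf had 898, fewer than its first 3 h. For a change of embryo batch at 60 hpf, the log2 changes from 54 to 60 hpf and from 66 to 72 hpf had a Pearson correlation across genes of 0.101 (Spearman 0.322; genes are not independent replicates), at the bound of 0.1 set in advance. The labels name no batch, and on the leading component the 60 hpf libraries (213.2 and 202.9) lay between those of 54 hpf (127.7 and 122.9) and 66 hpf (254.2 and 257.6). The correlation at its bound decides nothing. A batch from 60 hpf on would hold all later libraries too, so their places on the component do not exclude it. Such a batch would coincide with time and cannot be told apart from a faster developmental change.

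The rise of SLC12A3, WNK1 and SLC5A8 led to the hypothesis that a wider set of renal tubule and ionocyte transport genes rises from 48 to 72 hpf. A list of 75 such genes, without those that led to it, had 20 rising and 11 falling (median log2 change 0.20, camera p = 0.175, or 0.127 with an estimated correlation). The bound written in advance counts a p over the threshold against the hypothesis, so the prediction for the list as a whole was not met. Such a p does not show that the list moved like other genes, and a rise of a part of it was not tested. Among its members CUBN (PM18501, 1 of 4 models, another of which, PM05543, fell from 10.6 ± 0.637 to 2.86 ± 0.105 CPM) rose from 0.586 ± 0.0718 to 625 ± 12.3 CPM and BSND (PM18962) from 0.512 ± 0.0329 to 354 ± 1.92 CPM, while SLC4A2 (PM03993, 1 of 3 models) fell from 112 ± 0.167 to 8.67 ± 3.09 CPM. Lampreys are known to lose germ line sequences from somatic cells, and a loss of whole sequences from the assembly would make their genes fall together. Among 87 sequences with at least 20 tested genes the highest share called lower from 3 to 72 hpf was 52.2%, under the 80% predicted. In that sequence (74_unloc.1) 12 of 23 genes fell and 1 rose. Genes without counts at 3 hpf cannot be called lower, so a lost sequence could miss the bound and a loss is not excluded. Shorter sequences were not tested.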
